A study of Mus musculus with 8 samples.

How the data were processed

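RNA was measured in 8 libraries from sorted jejunal epithelial cells of female Sox9-EGFP mice on a C57BL/6J background. The labels place 4 animals in the conventionalized group and 4 in the germ-free group, and give each animal a littermate pair (A to D) with 1 animal of each condition. Cells positive for Annexin-V, CD31, CD45 or Sytox-blue were gated out, and the cells kept had a low level of the Sox9-EGFP reporter. Libraries were made by the authors from 10 ng of total RNA with a SMARTer Ultra Low Input kit and Nextera XT, and were sequenced as 100 bp single-end reads, with 4 libraries pooled at random per lane. Which library was on which lane is not given in the sources used here, so lane was not used.

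The submitters' processing notes list Trimmomatic 0.36, STAR 2.4.2a, R 3.3.1, DESeq2 1.12.4 and the build mm10, and the authors' series text names Salmon, edgeR and a minimum of 10 CPM (counts scaled to a common library total). The deposited values are a normalized signal per gene, not raw counts. They are estimated counts divided by the authors by a size factor per library and, for genes with several transcripts, by a factor per gene and library. This was read from the values. In 27909 genes with 1 annotated transcript, 99.8% of values were whole multiples of 1 step per library within a tolerance of 0.02, against 22.9% in 20149 genes with several transcripts. The steps ran from 0.736 to 1.35. Whole reads cannot be recovered for the genes with several transcripts, so the count tests planned before the data were examined were replaced by a test for continuous values: edgeR and DESeq2 were not run.

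The table held 48440 genes, of which 48058 were matched to a symbol and position in the GENCODE M21 annotation of GRCm38 (mm10), and 10128 were at 0 in every library. All 8 columns were mapped to a library by the label titles. Totals on an approximate read scale, that is, the deposited totals divided by each library's step, ran from 6209041 to 19139685. Values were scaled to CPM with TMM factors (trims of 30% of log ratios and 5% of intensities), computed from the published formula in R 4.3.3. The 10053 genes with at least 10 CPM in at least 4 libraries were tested as log2(CPM + 0.5). The pseudocount shrinks the fold changes of genes with low values. CPM values carry no information on depth per gene, and reads made by PCR without molecular identifiers are not independent molecules.

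Conventionalized and germ-free libraries were compared with limma 3.58.1 (trend and robust empirical Bayes, condition as the only term), with two-sided p-values adjusted by the Benjamini-Hochberg method and called under 0.05. Every adjusted p for a gene is from limma, with n = 4 animals per group. Lists of cell-type markers and pathways, 28 in all, were fixed before the data were examined, as were the main filter, the threshold, the alternatives planned and the rule for naming genes. The 27 lists with tested members were compared with the other genes by camera (preset correlation 0.01, two-sided, adjusted over the lists). With a correlation estimated per list, 0 lists passed in camera, 2 having an unadjusted p under 0.05. The self-contained test fry gave 0 lists after adjustment, with 7 at an unadjusted p under 0.05. Member counts are given over all genes and adjusted over the list alone. Scores and shares of lists were compared by exact two-sided permutation of the 8 libraries (70 assignments), whose smallest possible p is 0.0286, over 28 shares and 27 scores. These permutations ignore the littermate pairs, and the 16 assignments that keep them give no p under 0.125. The share of a list is its summed signal as a percentage of the library total.

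The genes named were chosen by 3 rules. The first took the 12 higher and 12 lower genes with the largest fold change among those called with the same sign in all 4 pairs, without placeholder symbols. The second took up to 4 members with the lowest p from each list, and the third always took Sox9, Lgr5, Olfm4, Ascl2, Mki67, Reg3g, Reg3b and Xist. This named 128 genes. Further list members given as examples, such as Chga, Ghrl, Tph1, Neurog3, Gip, Cdk1 and Aurkb, were chosen after their values were seen.

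Pairs come from the labels, which name the littermate pair of each animal, so the design pairs the libraries. The correlation within each pair of the deviations from the group means was 0.14 for pair A, -0.16 for B, 0.31 for C and -0.01 for D, so the values did not set littermates apart from other animals in all pairs. The main fit ignores the pairing of the design, and the littermate pair was fitted as a block only as an alternative. The block raised the calls from 495 to 1317, and the share of higher genes among them from 23.6% to 61.7%. Values with the block stand beside those results whose call or count it changes.

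The procedure was tested on simulated data with genes changed by a known amount in 4 libraries against 4. Over 5 simulations with 200 changed genes each and 10145.2 genes tested on average, limma recovered 73.4% of genes changed by a log2 fold change of 1 and 100% of those changed by 2. On average 7.6 calls per simulation were false, 4.20% of all calls. Simulated genes varied independently with a spread taken from the trend over genes, and no library stood apart. The changed genes were above the expression minimum in every library. The real libraries differ in these respects, so the recovered shares do not give the power in the real data. A gene not called there may still have changed by these amounts.

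Alternatives covered scaling (the deposited median-ratio scaling, upper quartile, library size only), voom with sample quality weights on values divided by each library's step, filters on low values, the littermate block, the threshold, each library and each pair left out, and the 50 most abundant genes left out. For lists, an estimated correlation and fry were added. Chosen after the data were seen were pseudocounts of 0.1 and 2 CPM, leaving out the 2 libraries that stood apart, scaling without genes that follow the enteroendocrine list, centring on transcript length and GC content, and the other scalings for lists. The small RNA libraries and other sorted populations that the series text describes were not analysed here.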

Results

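RNA was sequenced from sorted jejunal epithelial cells of 8 female mice that carry Sox9-EGFP, a green fluorescent reporter of the transcription factor Sox9. Cells with a low reporter signal were collected, a fraction enriched for the stem cells at the crypt base. Of each of 4 pairs of germ-free littermates, 1 animal stayed germ-free and the other was conventionalized. At 8 to 10 weeks of age it was moved to a conventional animal house, received fecal slurry by gavage and was studied 2 weeks later. The comparison asks how the microbiota affects the intestinal stem cell population. Depth on an approximate read scale, the deposited totals divided by a step read from each library's values, was 15998952, 9924726, 9363889 and 19139685 in the conventionalized libraries of pairs A to D, and 8758632, 11648530, 6209041 and 9747147 in the germ-free libraries. Values below are TMM-scaled CPM as mean ± SD (n = 4 animals per group), and fold changes are log2 of conventionalized over germ-free with their standard error (SE).

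Sox9, which marks the sorted fraction, was at 378 ± 109 CPM in conventionalized and 246 ± 82.7 CPM in germ-free libraries (log2 fold change 0.64, SE 0.36, adjusted p = 0.241). Xist, the transcript of the inactive X chromosome, ranged from 37.9 to 121.7 CPM, while the summed signal of Y-linked genes ranged from 0 to 0.889 CPM in these libraries from females. None of the 35 leukocyte markers in the table reached the expression minimum, and their share of the library was 0.00444 ± 0.00249% in conventionalized and 0.00595 ± 0.00151% in germ-free animals (exact permutation p = 0.314). The germ-free library of pair C stood apart from its group on overall expression and the conventionalized library of pair A on goblet cell markers. The former had a median correlation of 0.792 with the other germ-free libraries, against 0.871 to 0.943 for the other 7 libraries, and lay at the far end of the first principal component (60.7% of the variance). Goblet cell markers made up 4.11% of the conventionalized library of pair A and 0.205 to 0.996% of the others.

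Conventionalized animals had far more transcript of the antimicrobial lectins Reg3b and Reg3g, 17 of 40 mitosis genes were called higher in them and 14 of 25 enteroendocrine genes lower. Both lists passed camera with its preset correlation and not with an estimated one (adjusted p = 0.82 and 0.514). Reg3b was 129-fold and Reg3g 23.6-fold higher, with log2 fold changes of 6.32 to 7.74 and 3.87 to 5.22 when 1 library was left out, and the nucleoside transporter Slc28a2 was 4.57-fold higher. Neurod1, a transcription factor of enteroendocrine cells, was 4.82-fold and the enteroendocrine granule protein Scg5 4.27-fold higher in germ-free animals. limma called 117 genes higher and 378 lower in conventionalized animals among 10053 tested. Each of the 495 had the same sign in all 4 littermate pairs, which selection in these same libraries favours. With the littermate pair as a block the counts were 812 higher and 505 lower, and all 495 genes were also called.

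**Figure D1:**
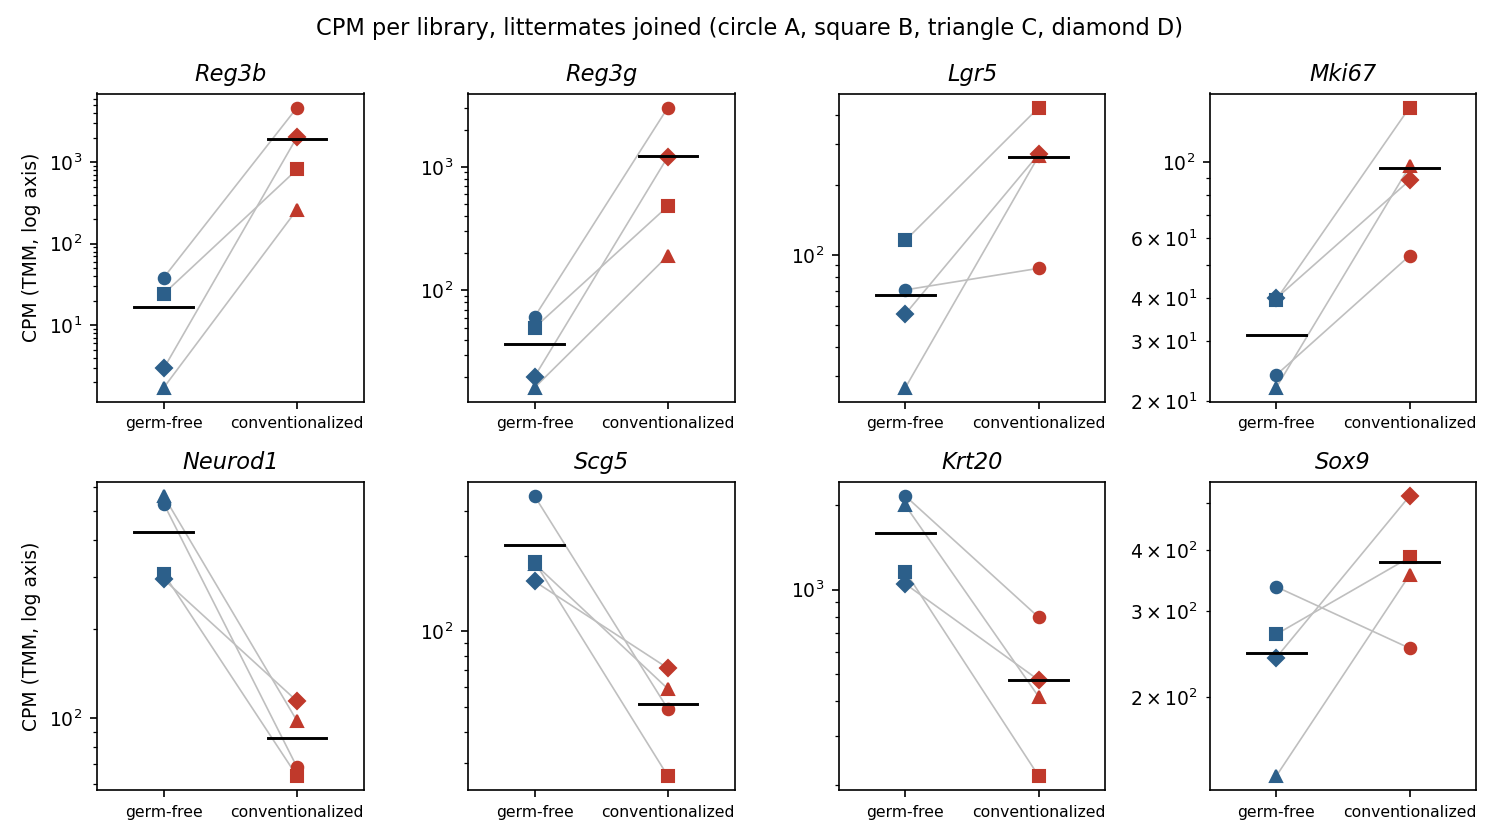
CPM of 8 genes in each library on a log axis, with germ-free and conventionalized littermates joined by lines and bars at the group means (n = 4). Reg3b lay between 262 and 4677 CPM in conventionalized animals and between 1.71 and 38.3 CPM in germ-free animals, while Neurod1 was lower in every conventionalized animal than in its littermate.

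The number of calls depended on single libraries. The sign of each call did not, which is weak support, since the genes were selected in these same libraries. Higher genes numbered 34, 15, 25 and 16 without the conventionalized library of pair A, B, C or D in turn, and 33, 461, 242 and 101 without the germ-free library of pair A, B, C or D. Lower genes numbered 278, 179, 234 and 278 without those conventionalized libraries and 179, 492, 417 and 399 without those germ-free libraries. Of the 117 higher genes, 9 were called in all 8 such fits and all 117 kept their sign, as did all 378 lower genes, of which 148 were called in all 8. Without the 2 libraries that stood apart, 103 of the 117 and 353 of the 378 were still called. The median log2 fold change over all tested genes was 0.32 with TMM scaling and 0.09 with library size only, and the list tests below are relative to the other genes. Higher genes were 23.6% of the calls, 39.2% with upper-quartile scaling, 47.3% by voom with quality weights and 61.7% with the littermate block. They were 12.6% with no filter, 19.2% with library size only and 20.2% after centring on length and GC content. With the block and centring they were 27.1%, and with libraries or pairs left out 4.75 to 53.9%. The condition went together with the move between animal houses, so these cannot be separated.

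Among genes of epithelial defence that respond to microbes, 3 of 16 tested members rose and 0 fell, and 5 rose when adjusted over the list alone and 5 with the littermate block. Reg3b (ENSMUSG00000071356.7, GRCm38 chromosome 6, 78370657 to 78373466) was at 1947 ± 1965 CPM in conventionalized and 16.8 ± 17.7 CPM in germ-free animals (log2 fold change 7.01, SE 0.99, adjusted p = 0.00577). Reg3g (ENSMUSG00000030017.2, chromosome 6, 78466269 to 78468872) was at 1223 ± 1268 and 36.9 ± 22.1 CPM (4.56, SE 0.70, adjusted p = 0.00577). Both rose in all 4 pairs, by log2 fold changes of 5.04 to 9.21 for Reg3b and 3.25 to 5.87 for Reg3g. Duox2, an epithelial oxidase that releases hydrogen peroxide, was the other member to rise, from 3.31 ± 2.91 to 17.4 ± 7.28 CPM (log2 fold change 2.49, SE 0.60, adjusted p = 0.0299). The inflammasome receptor Nlrp6 was at 566 ± 134 and 236 ± 119 CPM without passing the test (adjusted p = 0.0859, 0.021 with the block, 0.0163 by voom). The list as a whole had a median log2 fold change of 0.96 and passed camera (adjusted p = 0.0068; adjusted p = 0.924 with an estimated correlation). Reg3b and Reg3g are neighbouring paralogs, so reads can be assigned to the wrong family member and the division between them is uncertain. Without the germ-free library of pair C, the adjusted p was 0.0604 for Reg3b and 0.0953 for Reg3g, and for Reg3b it was 0.128 without the 2 libraries that stood apart and 0.0538 with no filter on low values. For Duox2 it was 0.132, 0.0697, 0.0739 and 0.0617 without the conventionalized libraries of pairs A, C and D and the germ-free library of pair A. Duox2 was tested in 7 of the fits without 1 library and called in 3 of them.

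Of the enteroendocrine genes, which serve hormone secretion, 14 of 25 tested members fell in conventionalized animals, 0 rose, and 23 fell when adjusted over the list alone. Neurod1 (ENSMUSG00000034701.9, chromosome 2, 79452521 to 79456751) was at 85.9 ± 24.0 CPM against 422 ± 142 CPM (log2 fold change -2.27, SE 0.34, adjusted p = 0.00548). Scg5 (ENSMUSG00000023236.7, chromosome 2, 113776362 to 113829121) was at 51.6 ± 19.0 against 219 ± 84.6 CPM (-2.10, SE 0.35, adjusted p = 0.00652). The granule protein Chga had log2 fold change -2.26 (adjusted p = 0.0267), the serotonin-synthesis enzyme Tph1 -2.35 (adjusted p = 0.0106) and the hormone gene Ghrl -2.22 (adjusted p = 0.0155). All 25 fold changes were negative, among them those of the progenitor factor Neurog3 (-0.93, adjusted p = 0.207) and the hormone gene Gip (-1.38, adjusted p = 0.125), which did not pass. The median was -1.81, and camera gave adjusted p = 4.51e-26 (adjusted p = 0.514 with an estimated correlation). With the littermate block, 18 members fell. The list made up 1.98 ± 0.79% of the conventionalized and 7.92 ± 2.51% of the germ-free libraries (exact permutation p = 0.0286, the smallest possible when the pairs are ignored, adjusted p = 0.1). Without the conventionalized library of pair B 9 members fell, and Neurod1 and Scg5 were called in each fit without 1 library.

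The cell-cycle genes called were all higher in conventionalized animals. In the list of mitosis and G2/M genes 17 of 40 tested members rose, 0 fell, and 40 rose when adjusted over the list alone, and 37 rose with the littermate block. The proliferation marker Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361) was at 95.9 ± 37.6 against 31.3 ± 9.80 CPM (log2 fold change 1.56, SE 0.34, adjusted p = 0.0192). The kinesin Kif23 (72.6 ± 10.3 against 18.8 ± 9.68 CPM, adjusted p = 0.0105) and Racgap1 (154 ± 18.8 against 54.1 ± 21.7 CPM, adjusted p = 0.0107), both needed for cytokinesis, were called in each fit without 1 library. The kinases Cdk1 (log2 fold change 1.88, adjusted p = 0.0289) and Aurkb (1.90, adjusted p = 0.0357) also rose. The list had median log2 fold change 1.57, and camera gave adjusted p = 5.95e-15 (adjusted p = 0.82 with an estimated correlation). In the list of DNA replication and G1/S genes 4 of 39 members rose (Rfc5, Pole, Cdc45 and Rrm1), 0 fell, 37 rose when adjusted over the list alone, and 32 rose with the block. That list had median 1.34 and camera adjusted p = 1.25e-09 (adjusted p = 0.924 with an estimated correlation). With a filter of the filterByExpr type, under which more genes are tested, 0 replication genes rose, and Rfc5, Cdc45, Pole and Rrm1 had adjusted p = 0.0501, 0.0527, 0.0569 and 0.0587. With upper-quartile scaling 28 mitosis and 9 replication genes rose, and by voom 34 and 25. The germ-free library of pair C had the lowest mean level of both lists; without it the medians were 1.124 and 0.831 and the members that rose numbered 32 and 10. They numbered 34 and 19 without the germ-free library of pair B. Without the conventionalized library of pair A, B, C or D, 5, 3, 2 and 3 mitosis genes rose and 0 replication genes, and without the germ-free library of pair A 4 and 0. Without the germ-free library of pair D 20 and 0 rose. Mki67 had adjusted p = 0.0746, 0.069 and 0.0603 without the conventionalized libraries of pairs B and C and the germ-free library of pair A, and 0.0684 with library size only.

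Stem cell genes gave few calls in the main fit. Among 28 tested active stem cell markers 1 rose, the R-spondin receptor Lgr5, 0 fell, and 15 rose when adjusted over the list alone. With the littermate block 12 rose, and by voom 6. Lgr5 (ENSMUSG00000020140.15, chromosome 10, 115450311 to 115587780) was at 263 ± 140 CPM against 67.1 ± 36.9 CPM (log2 fold change 1.94, SE 0.50, adjusted p = 0.0397). Its adjusted p was 0.124, 0.109 and 0.115 without the conventionalized libraries of pairs B, C and D, and 0.076, 0.111 and 0.0848 without the germ-free libraries of pairs A, C and D. It was 0.0557 by voom, 0.0648 after centring on length and GC content and 0.0517 with no filter. The markers Olfm4 (log2 fold change 1.52, adjusted p = 0.134) and Ascl2 (1.37, adjusted p = 0.121) did not pass. With 1 library left out their log2 fold changes ran from 0.89 to 1.86 and from 0.82 to 1.71. All 28 markers had positive fold changes with median 1.17, and camera gave adjusted p = 1.97e-05 (adjusted p = 0.924 with an estimated correlation). Without the germ-free library of pair C the median was 0.73. In the Wnt and R-spondin pathway list, which shares 11 tested members with the stem cell markers, 3 of 25 rose (Lgr4, Fzd7 and Lgr5) and 0 fell. In that list 6 rose and 1 fell when adjusted over the list alone or with the block, and 5 rose and 1 fell by voom. Its median was 0.80 (camera adjusted p = 0.0068; adjusted p = 0.924 with an estimated correlation) and 0.46 without the germ-free library of pair C. With library size only, Lgr5, Lgr4 and Fzd7 did not pass, at adjusted p = 0.0766, 0.0673 and 0.0952, nor did Lgr4 and Fzd7 with the filterByExpr-type filter (0.0504 and 0.056). Lgr4 and Fzd7 were each called in 3 of the 8 fits without 1 library. The reserve or injury-activated stem cell list (5 tested) held 0 calls by limma, 2 at an unadjusted p under 0.05, 2 by voom, 2 with the block, and 2 higher adjusted over the list alone, with median 0.26 (camera adjusted p = 0.753).

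**Figure D2:**
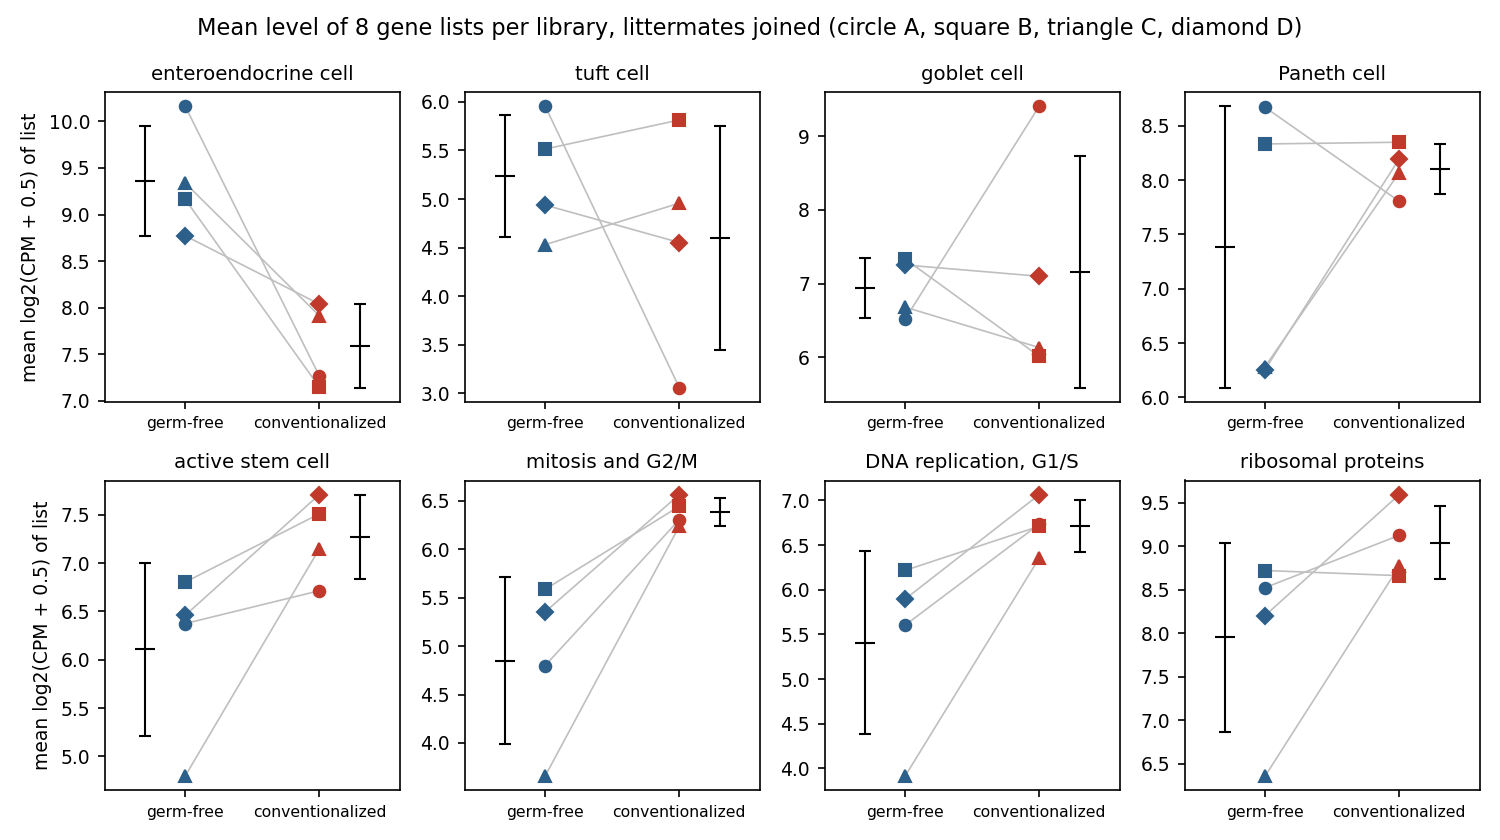
Mean log2(CPM + 0.5) of 8 gene lists in each library, with mean ± SD per group (n = 4). Enteroendocrine genes were at 9.36 ± 0.59 in germ-free and 7.59 ± 0.45 in conventionalized libraries, and mitosis and G2/M genes at 4.85 ± 0.86 and 6.39 ± 0.15.

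Most genes of translation and respiration had positive fold changes, and no single gene passed the test in the main fit. For the 83 cytoplasmic ribosomal protein genes limma called 0 members, and 0 adjusted over the list alone, with 58 higher at an unadjusted p under 0.05, 0 by voom and 3 with the littermate block. Those 3 were Rpl22 and the ribosomal-protein-like genes Rpl22l1 and Rpl7l1. Rpl22l1 was also called in 1 of the 8 fits without 1 library (adjusted p = 0.0499). All 83 fold changes were positive (median 1.09), among them Rpl22 (154 ± 54.3 against 67.2 ± 36.2 CPM, adjusted p = 0.114, 0.0379 with the block) and Rpl13a (630.0 ± 217 against 296 ± 149 CPM, adjusted p = 0.131), and camera gave adjusted p = 7.62e-09 (adjusted p = 0.924 with an estimated correlation). For 79 nuclear genes of oxidative phosphorylation limma called 0, and 0 adjusted over the list alone, with 24 higher at an unadjusted p under 0.05, 0 by voom and 2 with the block. Their median was 0.87 (camera adjusted p = 7.19e-06; adjusted p = 0.924 with an estimated correlation), with Ndufa9 at 426 ± 133 against 206 ± 109.7 CPM (adjusted p = 0.122, 0.0464 with the block). Both lists were lowest in the germ-free library of pair C, and without it the medians were 0.56 and 0.44. Within pairs A to D the mean score of the ribosomal list differed by 0.60, -0.06, 2.41 and 1.39. That of the oxidative phosphorylation list differed by 0.67, -0.25, 1.66 and 1.17. For 12 mitochondrially encoded genes limma called 0, with 0 at an unadjusted p under 0.05 and 0 by voom; their median was 0.33 (camera adjusted p = 0.715).

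Other epithelial markers gave few calls. Of 26 absorptive enterocyte genes 4 fell (the peptide transporter Slc15a1, the disaccharidase Sis, Cyp3a11 and the keratin Krt20) and 0 rose; adjusted over the list alone, 4 fell and 1 rose, and with the block 5 fell and 2 rose. Krt20 was at 475 ± 241 against 1592 ± 568 CPM (log2 fold change -1.82, SE 0.44, adjusted p = 0.0317), and without the conventionalized libraries of pairs B, C and D and the germ-free library of pair A its adjusted p was 0.112, 0.091, 0.0724 and 0.0904. Sis did not pass without the conventionalized libraries of pairs B (adjusted p = 0.0599) and C (0.0586), nor Cyp3a11 without the conventionalized library of pair B (0.0688) or the germ-free library of pair A (0.0902). Members that fell numbered 1, 2 and 2 without the conventionalized libraries of pairs B and C and the germ-free library of pair A. The median of the enterocyte list was 0.52, its mean -0.00433, and camera ranked it below the other genes (adjusted p = 0.0775). It was called lower without the conventionalized library of pair A (median -0.19, adjusted p = 0.00523) and without the germ-free libraries of pairs C (0.06, adjusted p = 0.0428) and D (0.15, adjusted p = 0.0442). Of 20 Paneth cell genes 1 rose, the pentraxin Mptx2 (134 ± 65.8 against 26.9 ± 26.6 CPM, log2 fold change 3.11, SE 0.78, adjusted p = 0.037), 0 fell, and 1 rose adjusted over the list alone; the list median was 0.62 (camera adjusted p = 0.45; 0.00717 without the germ-free library of pair A). The Wnt ligand Wnt3 did not pass in the main fit (adjusted p = 0.076). It fell with the littermate block (0.0448), with library size only (0.0468) and by voom (0.00917). Wnt3 also fell after centring on length and GC content (0.047) and without the 2 libraries that stood apart (0.0233). Mptx2 passed in 2 of the 8 fits without 1 library (log2 fold changes 2.31 to 3.73), with adjusted p up to 0.291 without the germ-free library of pair C. Nor did it pass by voom (log2 fold change 1.96, adjusted p = 0.21), with library size only (0.0558) or with the filterByExpr-type filter (0.0747). Under that filter camera called the Paneth list higher (adjusted p = 0.0206) with 0 members called. For 16 goblet cell genes limma called 0, with 1 higher at an unadjusted p under 0.05 and 0 by voom, and a median of 0.22 that camera ranked below the other genes (adjusted p = 0.639). Without the conventionalized library of pair A the goblet median was -0.67 and camera called the list lower (adjusted p = 0.00119).

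Of 16 tuft cell genes limma called 0, with 0 at an unadjusted p under 0.05 and 0 by voom. The tuft cell kinase Dclk1 was at 68.2 ± 60.8 against 103 ± 21.5 CPM (adjusted p = 0.219), and the list median was -0.76 (camera adjusted p = 2.98e-04; adjusted p = 0.924 with an estimated correlation). Without the conventionalized library of pair A, where this list was lowest, camera gave adjusted p = 0.143 at a median of -0.34. Of 3 tested endothelial and stromal genes 1 fell, Pecam1, which encodes the CD31 used in the gate (4.999 ± 3.34 against 19.9 ± 5.69 CPM, log2 fold change -2.03, SE 0.45, adjusted p = 0.0218), and 2 fell when adjusted over the list alone or with the block. The other 2 tested were Vim (log2 fold change -1.34) and Esam (0.33). All further members of the list, such as Cdh5 (0.418 against 1.88 CPM) and Kdr (4.31 against 5.21 CPM), did not reach the expression minimum. Pecam1 did not pass without the conventionalized library of pair B (adjusted p = 0.0688) or the germ-free library of pair A (0.061). That list passed camera (median -1.34, adjusted p = 0.0249; adjusted p = 0.551 with an estimated correlation), but not without the conventionalized library of pair A (adjusted p = 0.0739) or the germ-free library of pair B (adjusted p = 0.0555), with library size only (0.0592) or after centring on length and GC content (0.0622). Over the 27 lists 7 were called higher and 5 lower by camera. Of the 35 splits of the 8 libraries into groups of 4, 12 gave at least 12 lists, as did 3 of the 8 splits that part all pairs.

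**Figure D3:**
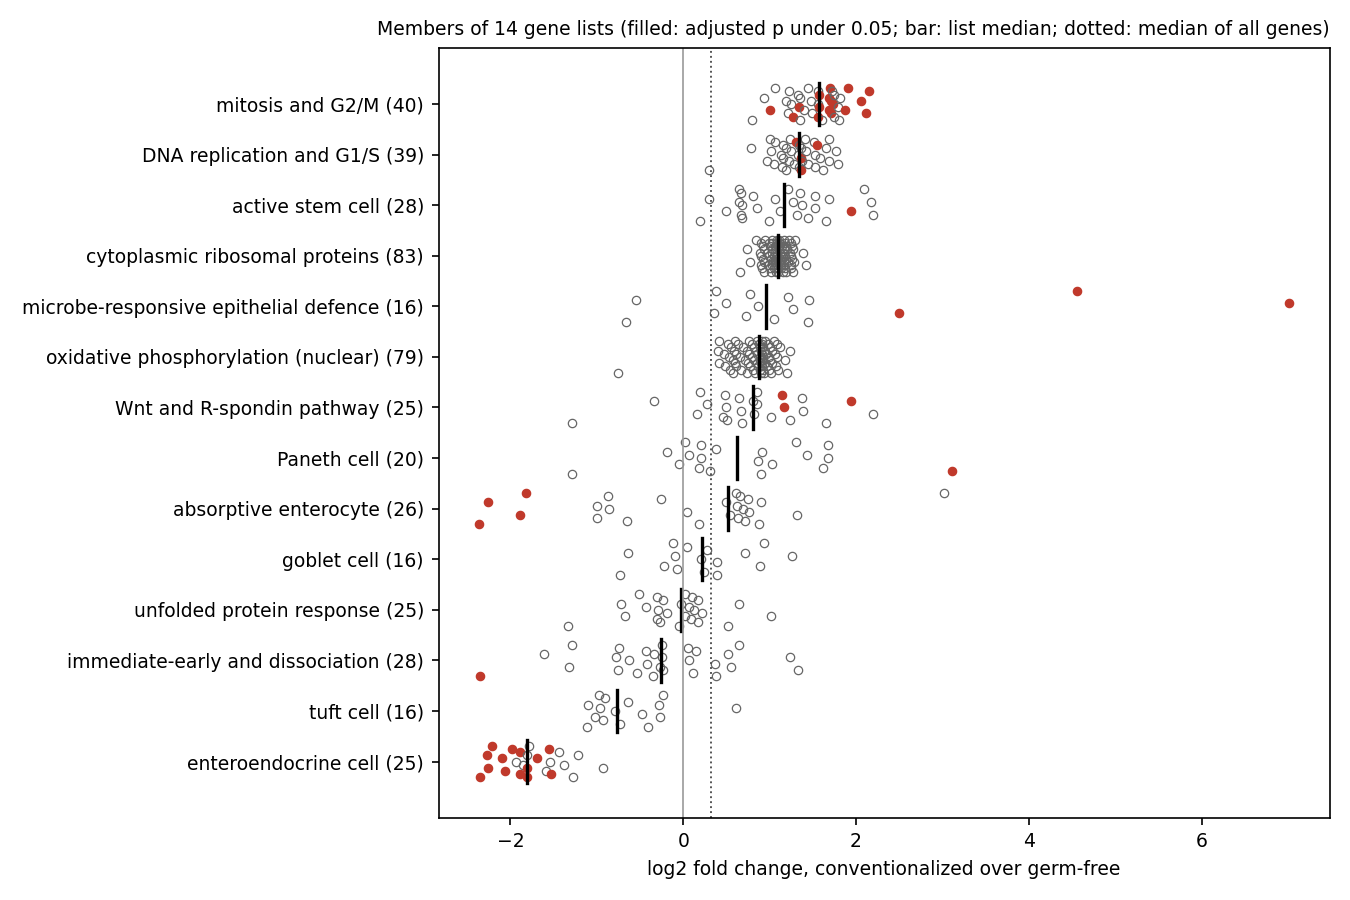
Log2 fold change of each tested member of 14 gene lists, conventionalized over germ-free, with filled points for adjusted p under 0.05, a bar at each list median and a dotted line at the median of all genes (0.32). All 25 enteroendocrine members lie below 0, and all 40 mitosis and G2/M members lie above 0.

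Of the called genes with the largest fold changes, the 12 lower ones were outside the lists, while many of the 12 higher ones were defence, Paneth or mitosis list members. Besides Reg3b, Reg3g, Mptx2 and Duox2, the higher genes were Syne4 (log2 fold change 2.62, SE 0.59), Oip5 (2.39), Cep55 (2.21), Slc28a2 (2.19), Ccnb2 (2.15), Kif23 (2.11), Ube2t (2.10) and Ndc80 (2.06). Slc28a2 (ENSMUSG00000027219.13, chromosome 2, 122426477 to 122461137) was at 49.0 ± 10.3 against 10.3 ± 1.84 CPM (SE 0.28, adjusted p = 0.00548). It was called in all 8 fits without 1 library, whereas Syne4, Oip5 and Cep55 were called in 3, Ube2t in 4, and Ccnb2 (1.398 to 2.501) and Ndc80 in 2. The lower genes were led by Pcp4l1 (3.94 ± 2.38 against 37.8 ± 8.27 CPM, log2 fold change -3.28, SE 0.45, adjusted p = 0.00548), Lrrn1 (-3.22), the serine protease Tmprss6 (-3.05) and Plk5 (-3.01). Next came the GLP-1 receptor Glp1r (-2.85), the ectonucleotidase Nt5e (-2.83), the secreted Wnt inhibitor Wif1 (-2.83), Sh3kbp1 (-2.77), Adgrd1 (-2.77), Synpo (-2.76), the sodium channel Scn3a (-2.75) and Serpina1c (-2.73). Of these 12, Tmprss6, Plk5 and Serpina1c were not called in every fit without 1 library, with adjusted p up to 0.086, 0.0921 and 0.177. Their log2 fold changes reached up to -2.45, -2.40 and -2.05 in those fits, and that of Sh3kbp1 up to -2.18. With a pseudocount of 0.1 CPM Tmprss6 was at -3.81 and was not called (adjusted p = 0.0563), so its place in this order depends on the pseudocount.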

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

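Among the tests below, the dilution test and the 2 counts of cell-cycle calls were chosen after the result was seen. The dilution test uses a t interval within pairs because an exact test that keeps the pairs cannot give a p under 0.125. Centring on transcript length and GC content, and upper-quartile scaling for a list, were chosen after the data were seen, with their predictions written before their results.

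Of 318 groups of 4 libraries examined (the log2 CPM of each named gene and the mean of each list, per condition), 11 held a library far from the other 3 by Dixon's criterion, fewer than the about 1 in 20 groups that chance alone would give. All 11 concern genes, and 5 of them are low values of the germ-free library of pair C. There, log2 CPM was 3.36 for Ier5 (others 5.03 to 5.34), 3.94 for Rpl22 (others 6.26 to 6.62), 3.38 for Hes1 (others 6.42 to 6.80), 5.77 for Sdhc (others 7.22 to 7.37) and 5.47 for Etfdh (others 6.46 to 6.64). The germ-free library of pair A was high for Lgmn (4.45; others 3.91 to 3.99) and Ly6g6f (5.24; others 4.11 to 4.21), and that of pair D was high for Clu (4.59; others 2.97 to 3.21). The conventionalized library of pair B was low for Usp18 (3.9985; others 4.42 to 4.49) and Sh3kbp1 (1.73; others 3.82 to 4.24), and that of pair D was high for Per2 (4.18; others 1.90 to 2.23).

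All 25 enteroendocrine genes had negative fold changes, with 14 called lower in conventionalized animals (median log2 fold change -1.81). Against technical sources, the median was -1.80 without the germ-free library of pair C, -1.79 with upper-quartile scaling and -2.23 after centring on transcript length and GC content. A larger share of enteroendocrine cells among the sorted germ-free cells remains a candidate explanation. It needs the members to move together, and 0 of 25 departed from the list mean between groups by limma (0 at an unadjusted p under 0.05, lowest adjusted p = 0.596, for Neurod1 by -0.50). With SEs of 0.17 to 0.62, departures of 0.84 for Neurog3 and -0.59 for Tph1 also went uncalled. The test could thus miss members that moved apart, and its result is weak support. Enteroendocrine cells are known to have a high Sox9-EGFP signal, so the low gate should hold few of them, and the gate itself was not tested. Less transcript per cell, with the microbiota or the animal house as its source, stays open and was not tested.

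Of the cell-cycle genes 21 of 79 were called higher in conventionalized animals (median log2 fold change of the 2 lists 1.41, SE 0.48). The SE beside these medians is that of the difference between groups in the lists' mean log2 CPM, with pairs ignored. Whether the germ-free library of pair C, or a trend in length and GC content, accounts for part of the size cannot be decided. The median was 0.96 (SE 0.23) without that library and 1.07 (SE 0.36) after centring. These fits share libraries with the main one, so the SEs do not measure the differences from 1.41. As the whole source of the calls that library and that trend are argued against: of 79 members 42 were called higher without that library and 20 after centring. With the littermate block the calls were 69, and 42 after centring. Dilution by enteroendocrine RNA as the whole source needs the other cell types to fall alike in germ-free animals. Within pairs the mean score of the Paneth, goblet, tuft and enterocyte lists differed by 0.07 (SE 0.22), and the cell-cycle score rose against it by 1.352 (SE 0.28, 95% interval 0.45 to 2.25, higher in 4 of 4 pairs). In pair A the goblet score differed by 2.89 and the tuft score by -2.90, which cancel in that mean. Against each of the 4 lists alone the interval lay above 0 for 1, the enterocytes, and included 0 for Paneth, goblet and tuft. Of the single lists only the enterocytes thus argue against dilution, and the test cannot decide by the others. More cycling cells under the microbiota, or a shift in which crypt cells the gate held, may account for the cell-cycle calls and were not tested.

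All 83 ribosomal protein genes had positive fold changes, with 0 called (median log2 fold change 1.09, with an SE of 0.58 defined as for the cell-cycle lists). The median was 0.56 (SE 0.26) without the germ-free library of pair C and 0.55 (SE 0.27) after centring on length and GC content, so that library's low values, or a trend with length, cannot be told apart from the condition as a source of about that difference. The fits share libraries, so these SEs do not measure the difference between the medians, and neither value decides. A biological change of translation genes stays open as well.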

How the results depend on the processing

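The alternatives chosen after the data were seen were the pseudocounts, the 2 libraries standing apart left out, scaling without genes that follow the enteroendocrine list, centring on length and GC content, and the other scalings for lists. The 117 higher and 378 lower genes became 91 to 173 and 311 to 552 under settings that use all libraries and are not given here. Higher genes numbered 263 with upper-quartile scaling, 496 by voom with quality weights, 45 with no filter (more genes tested), 812 with the littermate block, 448 with the block and a filter of the filterByExpr type, 518 at adjusted p under 0.1 (a looser threshold), 263 without the 2 libraries that stood apart and 298 with the block and centring. Lower genes numbered 209 with 10 CPM in all 8 libraries (fewer genes tested), 684 with centring and 802 with the block and centring. Leaving out libraries or pairs gave 3 to 461 higher and 27 to 492 lower genes. The lowest counts were without pair A and the highest without the germ-free library of pair B. Of the 27 lists, 12 passed; 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by fry (7 at an unadjusted p under 0.05), and 10 to 15 passed elsewhere. Where no construction is named, the cause was not tested.

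The genes whose sign turned, and the lists whose place against the other genes turned, were called in neither setting. The medians of 2 lists turned while camera called them lower than the other genes. The goblet median was -0.67 without the conventionalized library of pair A, -0.92 without pair A and -0.55 without the 2 libraries that stood apart (adjusted p = 0.00119, 5.01e-06 and 5.40e-05). The absorptive enterocyte median was -0.19 and -0.34 in the first and last of these (adjusted p = 0.00523 and 3.05e-05). The unfolded protein response median was 0.04, 0.18 and 0.05 without the conventionalized libraries of pairs B and C and the germ-free library of pair A, where its call was lost, and the tuft median was 0.02 without pair A (adjusted p = 0.577). Under voom Xist was at 0.28. Without the 2 libraries that stood apart Ccl6 was at -0.24, Krt19 -0.16, Spink4 -0.29 and Xist 0.42, and the medians of lists that changed place against other genes were 0.10 for MHC class I, 0.0626 for fatty acid oxidation, 0.18 for interferon-stimulated genes, -0.11 for mitochondrially encoded genes and -0.0107 for xenobiotic genes. With the filterByExpr-type filter these medians were 0.20 for Notch, 0.27 for apoptosis and p53 targets and 0.26 for goblet genes. With centring Esam was at -0.0843, mt-Atp8 -0.0568 and mt-Nd1 -0.14, with medians of -0.0513 for Paneth, 0.0443 for fatty acid oxidation, -0.17 for mitochondrially encoded and 0.0282 for reserve stem cell genes. When libraries or pairs were left out, values ran from -0.0924 to 0.55 for Krt19, -0.32 to 0.29 for Xist, 0.24 to 0.91 for Paneth, 0.16 to 0.60 for cholesterol synthesis, 0.21 to 0.56 for fatty acid oxidation, -0.92 to 0.67 for goblet, 0.26 to 0.68 for interferon-stimulated, 0.00483 to 0.33 for microRNA machinery, -0.00217 to 0.52 for mitochondrially encoded and 0.26 to 0.76 for xenobiotic genes. The cause was not tested.

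Of the 128 named genes, the block added 36 calls, and of the lists it added MHC class II and the circadian clock. It ended 0 calls and changed no other call among the lists. Of the 52 calls among the named genes, the filterByExpr-type filter ended 10 (Mptx2, Lgr4, Fzd7, Rfc5, Cdkn1a, Pole, Cdc45, Ccnb2, Nfil3 and Rrm1). No filter ended these and Reg3b, Tap1, Dll4, Per2 and Lgr5, with more genes tested in each case. Library size only ended 9 and added 7, voom ended 4 and added 17, centring ended 3 and added 15, and leaving out the 2 libraries that stood apart ended 5 and added 18. A pseudocount of 0.1 CPM ended 6. The unfolded protein response list was not called without the conventionalized libraries of pairs B (adjusted p = 0.147) and C (0.246) or the germ-free libraries of pairs A (0.0937) and B (0.0655), and the immediate-early list not without the conventionalized library of pair B (0.0978). With the filterByExpr-type filter these lists had adjusted p = 0.458 and 0.212, while Paneth (0.0206), MHC class I (0.0391) and MHC class II (0.0137) were called higher. The unfolded protein response list had adjusted p = 0.0502 with scaling without genes that follow the enteroendocrine list. The planned DESeq2 and edgeR alternatives were not run, since the values are not counts, and the transcript-level alternative has no transcript table to run on. Values near the expression minimum, and fold changes of low genes, are limited by depths of 6209041 to 19139685 on the approximate read scale.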

Other observations

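The comparison with splits that part all pairs was chosen after the result was seen, as was leaving out the 2 libraries that stood apart.

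Genes of the circadian clock included 1 that rose and 2 that fell among 13 tested, 2 that rose and 2 that fell when adjusted over the list alone, and 2 and 3 with the littermate block. The clock repressor Cry2 fell by 1.73 on the log2 scale (SE 0.32, adjusted p = 0.00825) and the repressor Per2 by 2.04 (SE 0.53, adjusted p = 0.0397), while the factor Nfil3 rose by 1.20 (SE 0.32, adjusted p = 0.0491). The list median was -0.34 (camera adjusted p = 0.0673, 0.0418 with the littermate block, 0.0189 without the germ-free library of pair A, and adjusted p = 0.654 with an estimated correlation). Time of tissue collection is not given in the sources used here. Cry2 was called in each fit without 1 library. Per2 was not called without the conventionalized libraries of pairs A (adjusted p = 0.0948), B (0.112) and C (0.112) or the germ-free library of pair D (0.0802), and Nfil3 was called in 2 of those 8 fits. Per2 did not pass by voom (0.084), nor Nfil3 with the filterByExpr-type filter (0.0634).

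Among the Notch genes 2 of 18 fell, the glycosyltransferase Mfng (log2 fold change -2.20, adjusted p = 0.00814) and the ligand Dll4 (-1.23, adjusted p = 0.0388), 0 rose, and 3 fell adjusted over the list alone (median 0.20, camera adjusted p = 0.692, ranked lower). Of 24 apoptosis and p53 target genes 1 fell, the cell-cycle inhibitor Cdkn1a (-1.34, adjusted p = 0.0465), with 0 adjusted over the list alone (median 0.27, camera adjusted p = 0.59, ranked lower). Of 29 interferon-stimulated genes 1 fell, the ISG15 protease Usp18 (20.002 ± 3.05 against 85.4 ± 23.4 CPM, log2 fold change -2.04, SE 0.28, adjusted p = 0.00548), 0 rose, and 1 fell adjusted over the list alone (median 0.54, camera adjusted p = 0.702). The peptide transporter Tap1 rose (log2 fold change 1.36, adjusted p = 0.0299) as 1 of 22 MHC class I genes, with 2 adjusted over the list alone (median 0.34, camera adjusted p = 0.639, and called higher at 0.0391 with the filterByExpr-type filter). For 10 MHC class II genes limma called 0, with 3 higher at an unadjusted p under 0.05, 0 by voom and 1 with the block, and a median of 1.19 (camera adjusted p = 0.0775, 0.0296 with the block, and adjusted p = 0.924 with an estimated correlation). That list was called without the conventionalized library of pair A (adjusted p = 0.0351), without the germ-free libraries of pairs B (0.034) and D (0.038), with the filterByExpr-type filter (0.0137) and without the 2 libraries that stood apart (0.0444). Its median ran from 0.47 to 1.53 with 1 library left out and was 0.56 without those 2 libraries. With the block, 2 rose and 3 fell among the Notch genes, 1 and 2 among the p53 targets, 4 and 1 among the interferon-stimulated genes, and 4 of the MHC class I genes rose. Reads of the H2 genes are shared between near-identical family members. Of the calls in this paragraph Usp18 and Mfng held in each fit without 1 library, Dll4 and Tap1 in 4 of 8 and Cdkn1a in 3 of 8. Cdkn1a did not pass with the filterByExpr-type filter (0.0565), nor Dll4 (0.116) and Tap1 (0.0832) with no filter.

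Among 28 immediate-early and dissociation genes 1 fell, the small heat shock protein Hspb1 (log2 fold change -2.35, SE 0.54, adjusted p = 0.0253), as did 1 adjusted over the list alone (median -0.26, camera adjusted p = 0.00519; adjusted p = 0.924 with an estimated correlation). Hspb1 was called in 4 of the 8 fits without 1 library, with adjusted p up to 0.208 and log2 fold changes of -2.72 to -1.67, and not by voom (0.0582). The block gave 1 higher and 4 lower. For 25 unfolded protein response genes limma called 0, with 1 higher and 2 lower at an unadjusted p under 0.05 and 1 by voom and 1 lower with the block, and camera gave adjusted p = 0.0429 at a median of -0.02 (adjusted p = 0.924 with an estimated correlation). For 25 genes of fatty acid oxidation (3 higher and 2 lower at an unadjusted p under 0.05; 1 by voom), 24 of cholesterol synthesis (4 and 1; 1 by voom), 26 of the xenobiotic response (4 and 3; 2 by voom) and 18 of the microRNA machinery (3 and 0; 0 by voom), limma called 0 and 0 adjusted over the list alone. Their medians were 0.40, 0.38, 0.57 and 0.22, and their camera adjusted p values 0.92, 0.715, 0.733 and 0.753. The block called 2, 3, 3 and 1 of them.

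A hypothesis is that many genes lower in conventionalized animals follow the amount of enteroendocrine RNA. With the group means removed, the 364 lower genes outside the list had a median correlation of 0.52 with the enteroendocrine score over the 8 libraries, against 0.07 for 10028 tested genes outside the list and -0.04 for the 117 higher genes. Of the 364, 52.7% had a correlation above 0.5, against 11.9% of the 10028. Genes are not independent replicates, and no test over the 8 libraries was run here. The values are consistent with a share of the lower genes being carried by enteroendocrine cells in the sorted fraction, but a change within cells that varies in parallel gives the same correlation.

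Other groupings of the 8 libraries were counted for the calls. The labels pair the littermates, so the real split was set against the 8 splits that part all 4 pairs, which are too few for a share under 0.05. Among these 8, 1 split, the real one, gave as many genes in either direction, 117 higher and 378 lower, against 0 in the highest other. Every split but the real one mixes the conditions within its parts. A difference between conditions then widens the spread within parts and works against calls, so the 0 does not show what unrelated groups would give. The 12 lists of the real split were reached by 3 of the 8 splits, itself included, with 14 the highest other. The other splits keep littermates together in at least 2 pairs. Over all 35 splits into 4 and 4, limma called 0 genes in each of the 34 others, which had up to 2797 genes at an unadjusted p under 0.05, against 2793 in the real split, and none was run with another tool. For the lists, 12 of the 35 gave at least 12, the highest other giving 16. Since list members move together in each library, camera with a preset correlation calls lists in other groupings too, at least 7 in each of the 34.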
